A study of Mus musculus with 16 samples.

How the data were processed

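Total RNA from sorted tumor cells was sequenced in 16 libraries, per the labels' protocols. RNA was taken up with Direct-zol columns with DNase treatment on the column, and libraries were made with a stranded total RNA kit that removes ribosomal RNA. Each library was assigned to a line (B16 or R499) and a genotype (control or STAT1 knockout) from its title and genotype label. The groups held 3 B16 control libraries (replicates 1, 4 and 5), 5 B16 knockout libraries, 3 R499 control libraries (replicates 1, 2 and 4) and 5 R499 knockout libraries. The titles call the control cells cas and the genotype label calls them wild type. The labels do not say whether the cells were sorted from cultures or from tumors, how the knockout was made, or that replicates came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical.

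The values deposited by the authors are on a log2 scale: regularized log (rlog) values per gene and library, per the file names, in which library size has been scaled out and low counts are drawn towards the gene's mean. A fold change of a weakly expressed gene is therefore understated. cutadapt 1.18, STAR 2.5.2a, Salmon 0.13.1, DESeq2 and the build GRCm38 are named without role or order, per the submitters' processing notes. Which of STAR and Salmon gave which deposited table, the DESeq2 version and its settings are not given in the sources used here. There were 2 deposited log2 tables of the same 16 libraries. The larger held 24211 genes and was used throughout, and the other held 22021, of which 20397 were in both. The choice was made before any difference between groups was computed, because the smaller table lacks the mitochondrially encoded genes. All value columns were matched to a library by name, and 24170 gene identifiers were matched to symbols. Positions and gene types came from an annotation of GRCm38. No counts were analysed here, so the depth of each library is unknown. No interval from counting error can be given, and the precision of each value is read from the spread between libraries alone.

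Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a mean per group over all 16 libraries, so that the groups shared an estimate of the spread. The empirical Bayes step used a mean-variance trend. Genes with a mean over all libraries above 3 on the rlog scale were tested, which left 13806 genes, 11300 of them protein-coding. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene was called changed at an adjusted p under 0.05 with no minimum fold. The 5 comparisons were knockout against control in B16, knockout against control in R499, R499 against B16 among control cells, R499 against B16 among knockout cells, and the difference between the 2 knockout effects. The overlap of genes higher in R499 control cells with genes lower in R499 knockout cells was also counted. Both lists use the R499 control libraries, so 100 data sets with unchanged groups were simulated to give the overlap, correlation and covariance under shared libraries. In each, the genes with the smallest p in a direction were taken up to the observed list length, with no threshold.

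Of 30 gene lists written from general knowledge, 20 had at least 5 tested members: type I interferon antiviral genes; interferon gamma GTPases, chemokines and regulators; MHC class I antigen presentation; checkpoint and costimulatory ligands; interferon receptor and JAK-STAT components; nucleic acid sensing; NF-kB and inflammatory genes; melanocyte pigment genes; dedifferentiated, mesenchymal-like melanoma genes; cell cycle; hypoxia and glycolysis; oxidative phosphorylation; integrated stress response and ER stress; p53 targets; dissociation and immediate early genes; interferon-linked chromatin regulators; macrophage and monocyte, fibroblast and endothelial markers; and mitochondrially encoded genes. The other 10 had fewer tested members and no test was made of them. Each list was tested with limma's camera with a preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation. Counts of changed members are given over all genes tested and adjusted over the list alone. fry, which asks whether the members of a list move on balance in one direction, was an alternative.

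The rule for named genes took Stat1 in every library. For each comparison it took the 6 largest rises and the 6 largest falls among changed genes whose groups did not overlap, without predicted gene models. For the difference of knockout effects the overlap condition was dropped. It took the 4 members with the smallest p in the direction of the list from each list past its camera test. For the overlap it took the 8 genes with the largest smaller difference. It also took 13 genes whatever their result, namely Stat1, Irf9, Irf1, Isg15, Oas1a, Ifit1, H2-K1, B2m, Tap1, Cd274, Lgals9, Mitf and Tyr, and 5 signs of other cells, namely Ptprc, Csf1r, Cd3e, Col1a1 and Pecam1. Isg15, Ptprc and Csf1r lay below the filter, with means of 2.65, 2.48 and 0.14 on the rlog scale, and Cd3e was not analysed here. The groups, tests, gene lists, this rule and most alternatives were set before the data were examined.

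The alternatives were no filter on low values, a filter at 5, quantile normalization, centring of each library on its median, no mean-variance trend, a robust variance estimate, library quality weights (statmod 1.5.0), only the libraries compared, the other deposited table, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Protein-coding genes only, the mean level of 167 small non-coding RNA genes as a covariate, and B16 knockout replicates 4 and 5 left out together were added after seeing the data. Counts of changed genes were also compared over other splits of the libraries. Chromosomes were scanned in windows of 50 neighbouring protein-coding genes against 1000 shuffled gene orders. In simulated data of 13806 genes, with 50 genes changed per size, a log2 change of 1 was recovered for 90% of genes for knockout in B16, 98% for knockout in R499, 94% for R499 against B16 control cells, 100% for R499 against B16 knockout cells and 94% for the difference of effects. A log2 change of 0.5 was recovered for 76%, 86%, 86%, 82% and 44% in the same order, with 8 to 10 false calls. The simulated noise was normal and independent, with the same spread of a gene in all groups. Changes were added on the rlog scale, so shrinkage of weak genes and noisier libraries were left out, and real recovery may be lower. Each comparison was simulated once, so small differences between these shares can be chance. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.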

Results

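Gene expression was measured by sequencing of total RNA in sorted tumor cells of 2 mouse melanoma lines on a C57BL/6 background. B16 is a transplantable melanoma line in wide use, and R499 is known as a B16 subline that resists immune checkpoint blockade, the antibody therapy that releases T cells from inhibitory receptors. Each line was studied as control cells (3 libraries) and as STAT1 knockout cells (5 libraries), with no treatment. STAT1 is the transcription factor that carries signals from the type I and type II interferon receptors to interferon-stimulated genes. The comparisons ask which transcripts depend on STAT1 in each line, how the lines differ with and without it, and whether the genes that stand higher in R499 are those that fall when STAT1 is lost. Values are rlog expression on a log2 scale, whose mean over tested genes lay between 7.55 and 7.61 in every library. Differences are given in log2 with their standard error (SE) and the limma p-value adjusted by Benjamini-Hochberg.

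Stat1 (ENSMUSG00000026104, GRCm38 chromosome 1, 52119440 to 52161865, plus strand) was lower in every knockout library than in every control library. Its rlog values were 10.26, 10.43 and 11.55 in B16 control replicates 1, 4 and 5, and 8.64, 8.65, 8.62, 8.79 and 9.07 in B16 knockout replicates 1 to 5. In R499 they were 11.57, 10.84 and 11.52 in control replicates 1, 2 and 4, and 8.55, 9.14, 8.66, 8.64 and 8.40 in knockout replicates 1 to 5. Stat1 fell 3.97-fold in B16 knockout cells (log2 difference −1.99, SE 0.245, adjusted p = 0.000122) and 6.2-fold in R499 knockout cells (−2.63, SE 0.245, adjusted p = 2.66e-06). The fall differed between the lines by −0.64 (SE 0.346, adjusted p = 0.45), which did not pass the threshold. Stat1 transcript remained measurable in all 10 knockout libraries, and transcript level does not measure STAT1 protein.

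**Figure D1:**
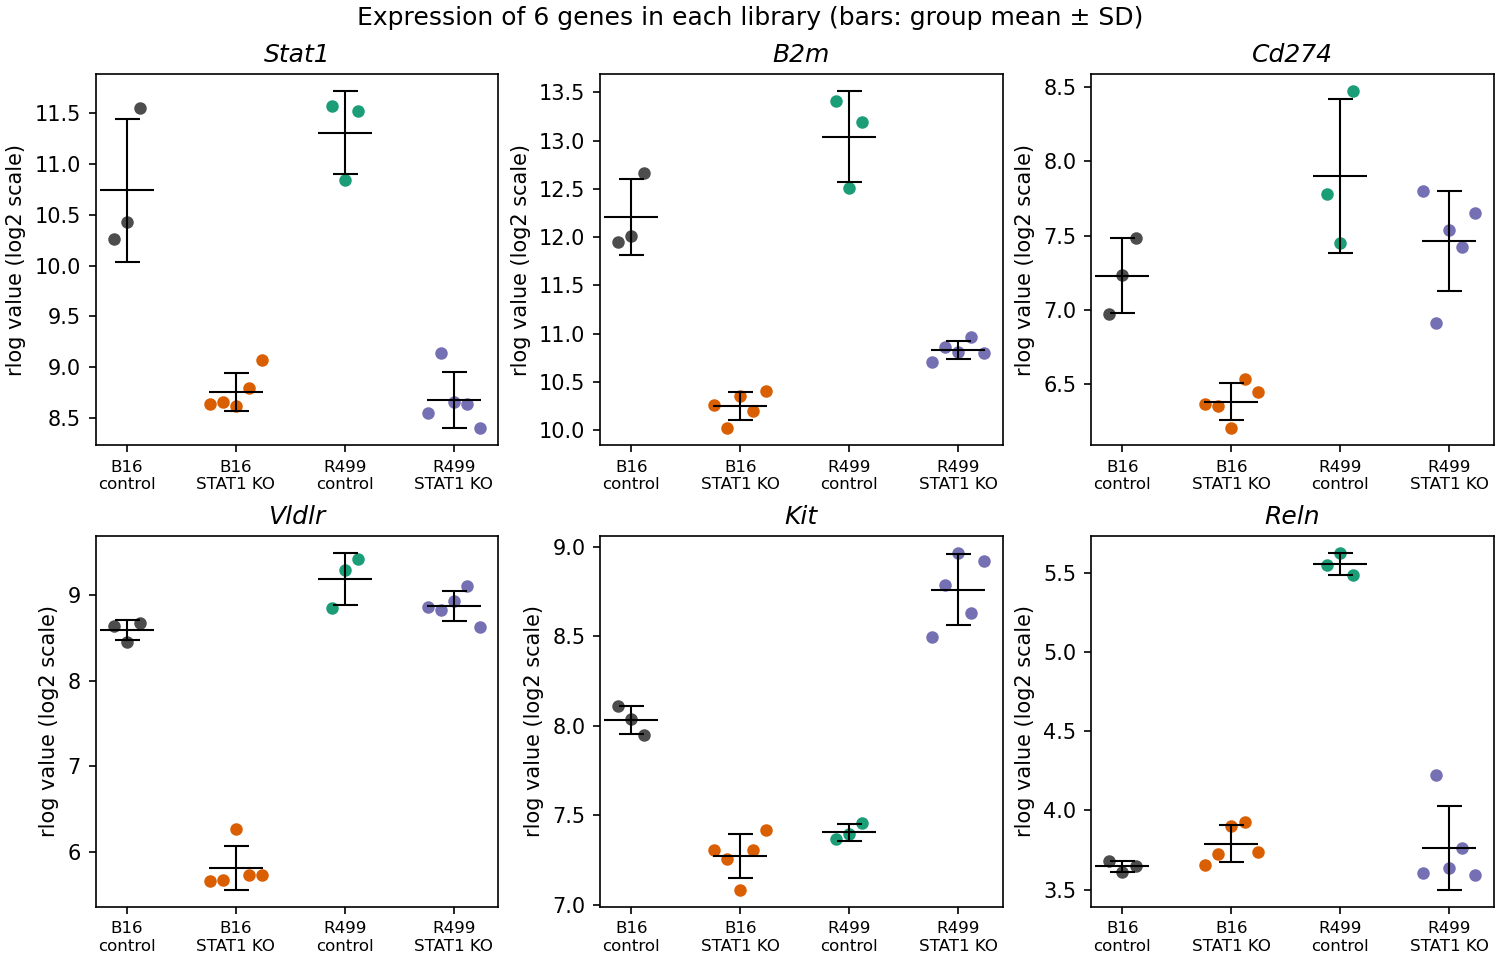
Expression of Stat1, B2m, Cd274, Vldlr, Kit and Reln in each of the 16 libraries, on the rlog (log2) scale, by group; points are libraries, and bars give the group mean ± SD (n = 3 control and 5 knockout libraries per line). All 10 knockout libraries sit below 9.2 for Stat1 and all 6 control libraries above 10.2, Vldlr is low in B16 knockout cells (mean 5.81) and near 9 in R499 knockout cells (8.87), Kit moves in opposite directions in the lines, and Reln is high in R499 control cells (5.55) only.

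In B16, STAT1 knockout cells had lost much of their interferon-stimulated transcription. Tgtp2, an interferon-induced GTPase of defence against intracellular pathogens, fell 13.6-fold (log2 difference −3.77, SE 0.322, adjusted p = 3.02e-06, n = 3 control and 5 knockout libraries). Related GTPases followed, with Iigp1 at −2.82 (SE 0.351), Tgtp1 at −2.65 (SE 0.35), Gbp7 at −2.56 (SE 0.225) and Gbp6 at −2.56 (SE 0.327). Vldlr, a lipoprotein receptor that also binds reelin and is not a classical interferon target (chromosome 19, 27216484 to 27254231), fell 6.86-fold (−2.78, SE 0.148, adjusted p = 2.81e-08). The largest rises were smaller: Lurap1l rose by 1.24 (SE 0.128, adjusted p = 1.86e-05), and Osmr, the oncostatin M receptor subunit, by 0.89 (SE 0.141, adjusted p = 0.00132). Papss2, which makes the sulfate donor of sulfotransferases, rose by 0.83, Abca13 by 0.79, Enah, an actin regulator, by 0.67 and the transcription factor Ets2 by 0.65.

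Of 40 tested type I interferon antiviral genes in B16, 33 fell and none rose (37 lower when adjusted over the list alone), with a median of −0.96. Examples were Ifit3 (−2.16), Ddx58, which encodes the RNA sensor RIG-I (−1.81), Samd9l (−1.13) and Oas1g (−0.78). Among the genes fixed in advance Ifit1 fell by 1.93 and Oas1a by 0.94. Of 21 interferon gamma GTPases, chemokines and regulators, 17 fell (19 adjusted over the list alone), including Irgm2 and Ifi47 at −2.23 each and Irf1, a transcription factor of the interferon response (−0.80, adjusted p = 0.0345). Of 19 genes of MHC class I antigen presentation, 8 fell (14 lower and 1 higher adjusted over the list alone): B2m, the light chain of MHC class I (chromosome 2, 122147686 to 122153083), fell by 1.96 (SE 0.174), the heavy chains H2-D1 by 1.13 and H2-K1 by 1.05, and the peptide transporter Tap1 by 1.38. These 3 lists passed camera (adjusted p = 3.34e-67, 6.27e-36 and 7.37e-15), and adjusted p = 0.0153, 0.0365 and 0.0365 with an estimated correlation. Of 14 nucleic acid sensing genes, 4 fell (8 adjusted over the list alone), namely Ddx58, Ifi203 (−2.18), Ifih1 (−1.22) and Tlr3 (−0.56), with camera adjusted p = 2.52e-08 and adjusted p = 0.0522 with an estimated correlation.

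Some single members of other lists also changed in B16 knockout cells. The partners of STAT1 in the interferon complex fell, with Irf9 at −1.04 (SE 0.0929, adjusted p = 3.86e-06) and Stat2, named after its value was seen, at −0.73; they were the 2 changed genes among 15 interferon receptor and JAK-STAT components, also 2 adjusted over the list alone, in a list that did not pass camera (adjusted p = 0.163). Cd274, which encodes the T cell inhibitory ligand PD-L1 (chromosome 19, 29367455 to 29388095), fell by 0.85 (SE 0.205, adjusted p = 0.0394, up to 0.225 over 21 alternatives, 9 of which ended the call). Lgals9, which encodes galectin-9, fell by 0.69 (SE 0.117, adjusted p = 0.00249). With H2-T23 (−0.60) they made 3 of 9 checkpoint ligands, also 3 adjusted over the list alone, without a call for the list (median 0.04, mean −0.19, adjusted p = 0.268). Jun (−0.41) and Ier2 (−0.28) fell among 16 immediate early genes (6 adjusted over the list alone), which respond to growth signals and to tissue dissociation, and Foxm1 (−0.42) among 30 cell cycle genes (2 adjusted over the list alone). The call ended for Ier2 in 15, Foxm1 in 8, Irf1 in 6, Jun and Tlr3 in 3 and Enah in 2 of 21 alternatives, and for Abca13 in 9 of 20. The immediate early list had adjusted p = 0.124 and the cell cycle list adjusted p = 0.516 with an estimated correlation. Mitf, the master regulator of melanocytes (0.30, adjusted p = 0.158), and the pigment enzyme gene Tyr (0.06, adjusted p = 0.78, and −0.04 under quantile normalization) did not pass.

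In total 297 of 13806 genes changed in B16, 78 higher and 219 lower, and 48 of the lower ones against 1 of the higher ones differed by at least 1 in log2. Fibroblast markers had a median of 0.27 and mitochondrially encoded genes of 0.33, with no member passing (also none adjusted over the list alone), camera adjusted p = 0.0126 and 0.00189, and adjusted p = 0.502 and 0.409 with an estimated correlation. Centring each library on its median gave 123 higher and 174 lower. The count was 175 without control replicate 4, 170 without control replicate 5, 192 with the B16 libraries fitted alone and 586 with library quality weights.

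In R499, the same groups of genes fell and more genes changed. Tgtp2 fell 24.6-fold (−4.62, SE 0.322, adjusted p = 1.44e-07, n = 3 and 5), followed by Iigp1 (−3.59, SE 0.351), Gbp6 (−3.44, SE 0.327), Gbp2 (−3.40, SE 0.297), Igtp (−3.25, SE 0.29) and Tgtp1 (−3.23, SE 0.35). The largest rise was that of Kit, the stem cell factor receptor of melanocytes (chromosome 5, 75574916 to 75656722; 1.35, SE 0.1, adjusted p = 2.99e-07). Ntrk3, a neurotrophin receptor, rose by 1.28 (SE 0.186), the cadherin gene Cdh13 by 1.08, Lifr, the leukemia inhibitory factor receptor, by 1.06 (SE 0.0986), the transcription factor Foxp2 by 1.01 and Adam23 by 0.99. The paralogs Tgtp1 and Tgtp2, Gbp6 and Gbp10, Oas1a and Oas1g, and the H2 heavy chain genes are similar in sequence. How reads shared between them were divided is not given in the sources used here.

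Of 40 type I interferon antiviral genes in R499, 37 fell (38 adjusted over the list alone), with a median of −1.16 and examples in Ddx58 (−2.48), Xaf1 (−2.33), Ifit1 (−1.66) and Oas1a (−1.46). Of 21 interferon gamma genes, 17 fell (18 adjusted over the list alone), with a median of −2.5, Ifi47 at −2.80, Irgm2 at −2.77 and Gbp7 at −2.73, while Irf1 did not pass (−0.67, adjusted p = 0.0511). Of 19 MHC class I genes, 15 fell (16 adjusted over the list alone), with a median of −0.93: B2m fell by 2.21 (SE 0.174, adjusted p = 5.44e-07), Tap1 by 1.75, H2-D1 by 1.74, H2-K1 by 1.61 and Erap1, which trims peptides, by 1.46. The camera adjusted p-values were 1.16e-64, 3.39e-34 and 5.55e-25, with adjusted p = 0.0089, 0.0305 and 0.0089 with an estimated correlation. Of 14 nucleic acid sensing genes, 7 fell (7 adjusted over the list alone), including Ifi203 (−2.40), Ifih1 (−1.40) and Zbp1 (−0.84), with camera adjusted p = 9.78e-08 and adjusted p = 0.0652 with an estimated correlation. Irf9 fell by 1.49 (SE 0.0929) and Lgals9 by 0.82 (SE 0.117), and Cd274 stood at −0.44 (SE 0.205, adjusted p = 0.248), which did not pass.

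Lists outside the interferon response moved by less in R499 knockout cells. Of their named genes Pbrm1 lost its call in 9, Ndufs2 and Cited1 in 7, Atp5c1 and Ezh2 in 6, Aldoc in 5, Bnip3 and Gpnmb in 4 and Mki67 and H2-T23 in 1 of 20 alternatives. Of 23 oxidative phosphorylation genes 4 fell (11 adjusted over the list alone), with Ndufs2 at −0.38 and Atp5c1 at −0.37. Of 25 hypoxia and glycolysis genes 4 fell (7 adjusted over the list alone), with Aldoc at −0.63 and Bnip3 at −0.56. Their camera adjusted p-values were 3.01e-07 and 9e-06, with adjusted p = 0.24 and 0.296 with an estimated correlation. Among 20 melanocyte pigment genes Tyr (−0.44, SE 0.0686, adjusted p = 0.000693), Cited1 (−0.57) and Gpnmb (−0.42) fell and Kit rose (6 lower and 2 higher adjusted over the list alone), with adjusted p = 0.316 with an estimated correlation; Mitf was at −0.26 (adjusted p = 0.144). The proliferation marker Mki67 (0.33, adjusted p = 0.011) was the 1 cell cycle gene that rose of 30 (also 1 adjusted over the list alone; list adjusted p = 0.46 with an estimated correlation). Ezh2 (0.30) and Pbrm1 (0.25) rose among 22 chromatin regulators (also 2 adjusted over the list alone; list adjusted p = 0.24 with an estimated correlation). Among 9 checkpoint ligands Lgals9 and H2-T23 (−0.89) fell and Cd276, named after its value was seen, rose by 0.39 (the same counts adjusted over the list alone), with adjusted p = 0.217 with an estimated correlation.

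Markers of stromal cells stood higher in R499 knockout than control libraries. Of 10 fibroblast markers 3 rose (8 adjusted over the list alone), the collagen genes Col3a1 (1.98, SE 0.536, adjusted p = 0.0424) and Col6a3 (0.81, SE 0.215) and the matrix proteoglycan gene Lum (0.62, SE 0.16), with a median of 0.61. Col1a1 was at 0.44 (adjusted p = 0.0945). Of 8 endothelial markers Kdr (0.40), Cdh5 (0.22) and Esam (0.14) rose (5 adjusted over the list alone), and Pecam1 was at 0.22 (adjusted p = 0.133). The call ended for Col3a1 in 12 and Col6a3 in 11 of 20 alternatives, and for Cdh5 and Esam in 9, Lum in 7 and Kdr in 5 of 19. Camera gave adjusted p = 3.63e-06 and 0.000549, with adjusted p = 0.217 and 0.103 with an estimated correlation. With fry the fibroblast and endothelial lists had adjusted p = 0.0191 and 0.00416. The 5 macrophage and monocyte markers had a median of −0.02, and none passed (also none adjusted over the list alone). Altogether 705 genes changed in R499, 262 higher and 443 lower, or 313 and 334 when each library was centred on its median. The count was 427 without control replicate 1, 364 without control replicate 2, 1069 without knockout replicate 4, 459 without knockout replicate 5 and 1963 with library quality weights.

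**Figure D2:**
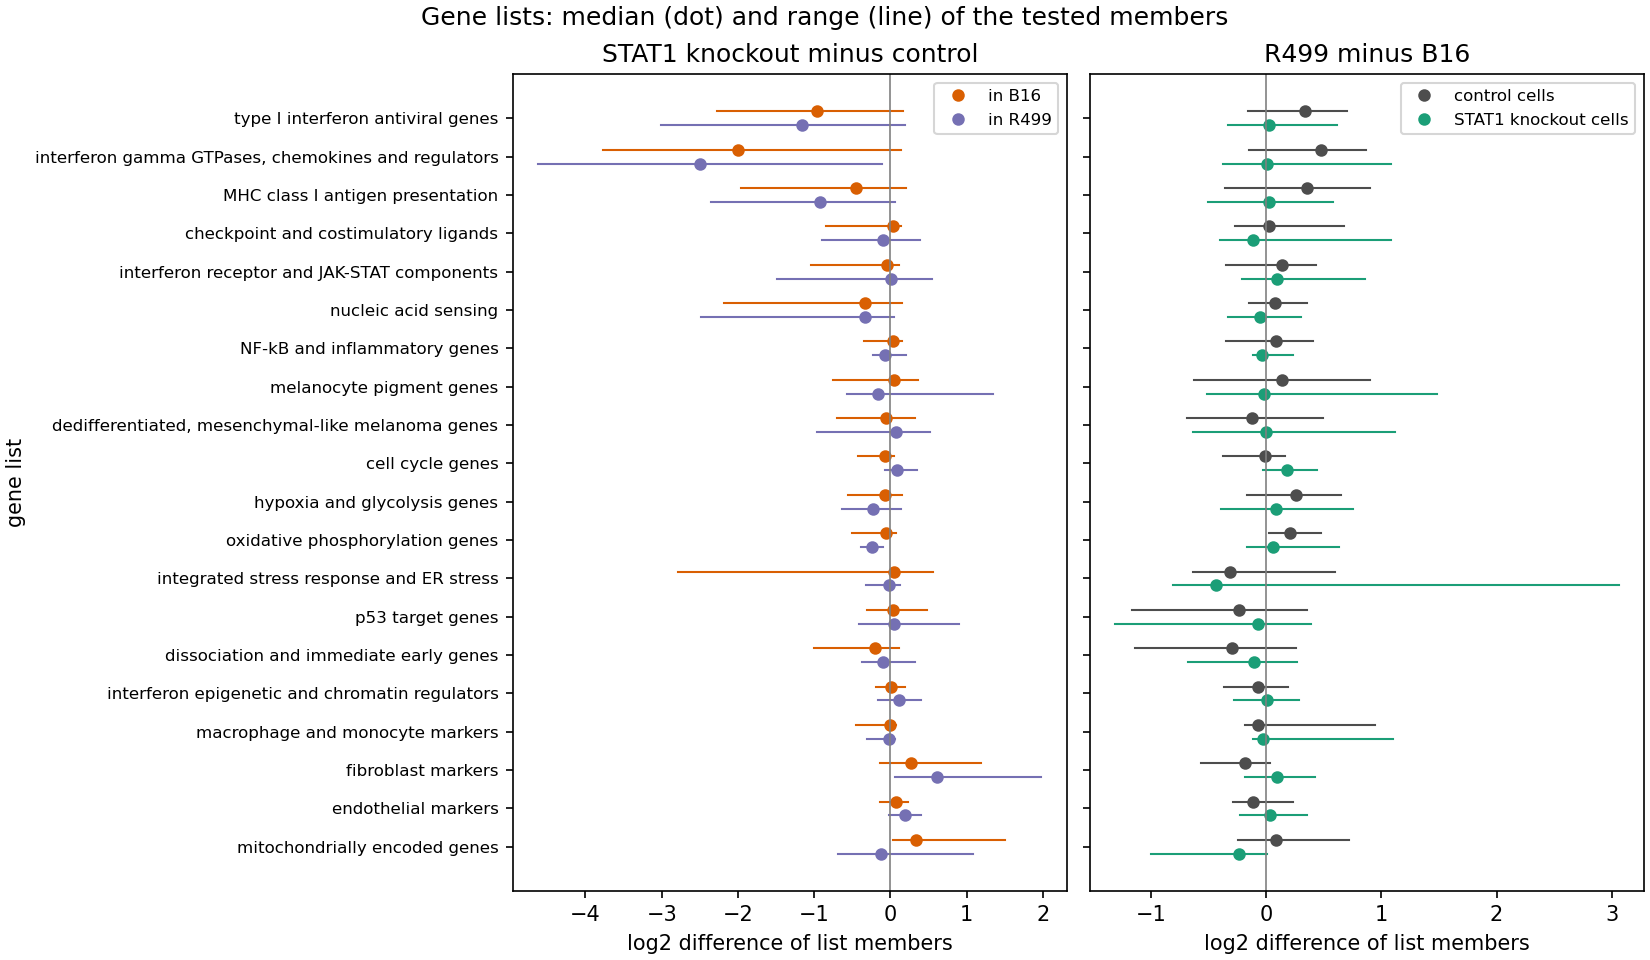
Median (dot) and range (line) of the log2 differences of the tested members of each gene list, for knockout minus control in both lines on the left and for R499 minus B16 in both genotypes on the right. The 3 interferon and MHC class I lists lie left of 0 in both lines (medians −0.96, −2 and −0.46 in B16, −1.16, −2.5 and −0.93 in R499), lie right of 0 for R499 control cells (0.34, 0.48 and 0.36) and lie near 0 between the knockout cells.

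The knockout comparisons in B16 and R499 share no library, and their calls overlapped. Of the genes that fell, 112 fell in both lines, against 7.03 for independent lists (219 × 443 / 13806). The 100 simulations without effects, with lists filled by rank to the observed lengths, gave at most 21. Of these 112, 56 belonged to the interferon and MHC class I lists and 56 did not, Irf9 among the latter, so the lists do not hold every interferon-linked gene. The second set, named after its values were seen, included Parp12 (−1.39 in B16 and −1.65 in R499), Ifi27 (−1.19 and −2.07), Mndal (−1.41 and −1.77) and the axon guidance gene Slit2 (−1.16 and −1.54). Only 9 genes rose in both lines (1.48 for independent lists, at most 7 in simulations), among them Osmr (0.89 and 0.64) and Adam23 (0.45 and 0.99). Across the 13806 genes the log2 differences correlated at 0.476, with a covariance of 0.0213 against 1.97e-05 simulated. This correlation is across genes, which are not independent replicates.

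The knockout effect itself differed between the lines for 176 genes, 93 with a higher and 83 with a lower effect in R499. The labels do not say whether the knockout cells were clones or pools, so differences between clones are not separated from effects of STAT1 in either line. Vldlr fell in B16 only by call (−2.78) and stood at −0.32 in R499 (SE 0.148, adjusted p = 0.243), a difference of effects of 2.46 (SE 0.209, adjusted p = 4.76e-06). Kit fell in B16 (−0.76) and rose in R499 (1.35), a difference of 2.11 (SE 0.142, adjusted p = 3.3e-07). Lifr (1.38, a call that ended in the other deposited table), the RNA-binding protein gene Rbms3 (1.33), the calcium channel gene Cacna1c (1.27, ended in 2 of 28 alternatives) and Ntrk3 (1.181, a call that ended in 11 of 28 alternatives) also had a higher effect in R499. Reln, which encodes the secreted glycoprotein reelin (chromosome 5, 21884454 to 22344702), fell in R499 (−1.79, SE 0.112) with 0.14 in B16 (SE 0.112, adjusted p = 0.662), a difference of −1.93 (SE 0.159, adjusted p = 4.03e-06). Mgarp (−1.53), the potassium channel gene Kcnj13 (−1.43), Lurap1l (−1.30), Tent5a (−1.25) and Carmil2 (−1.21) followed. Reln, Mgarp, Kcnj13 and Carmil2 differed between control cells by 1.91, 1.43, 1.33 and 1.20. Between knockout cells they differed by −0.02, −0.11, −0.10 and −0.01. For these genes the differing effect largely restates the difference between control cells. Reln stood near its knockout level already in B16 control cells, which left little room for a fall in B16.

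Few members of the fixed lists had a different effect in R499. The call ended for Pbrm1 in 17, Oca2 in 12 Ezh2 in 8, Tyr and Mki67 in 3 and Foxm1 in 2 of 28 alternatives and for Psmb9 and mt-Co1 in 9 of 27. Among MHC class I genes the immunoproteasome gene Psmb9 was lower by 0.60 (−0.60, SE 0.128, adjusted p = 0.0281), 1 of 19 (7 adjusted over the list alone), and the list median was −0.37. No type I interferon gene (6 lower adjusted over the list alone, median −0.20) and no interferon gamma gene (0 adjusted over the list alone, median −0.50) passed over all genes in limma, where 1824 of 13806 genes had an unadjusted p under 0.05. Foxm1 (0.77, SE 0.149) and Mki67 (0.51, SE 0.102) were higher among 30 cell cycle genes (3 adjusted over the list alone), Ezh2 (0.49) and Pbrm1 (0.39) among 22 chromatin regulators (also 2), Kit among 20 pigment genes with Tyr (−0.50) and Oca2 (−0.63) lower (1 higher and 5 lower adjusted over the list alone), and mt-Co1 was lower (−0.58) among 13 mitochondrially encoded genes (3 adjusted over the list alone). Camera called 12 of the 20 lists, and none held, with adjusted p between 0.469 and 0.535 with an estimated correlation. B2m (−0.25, adjusted p = 0.722), Cd274 (0.41, adjusted p = 0.581) and Irf9 (−0.45, adjusted p = 0.126) did not pass. The balance of 93 and 83 was 71 and 73 after centring on library medians. The count of 176 was 81 without B16 control replicate 4, 115 without R499 control replicate 1 and 669 with library quality weights.

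**Figure D3:**
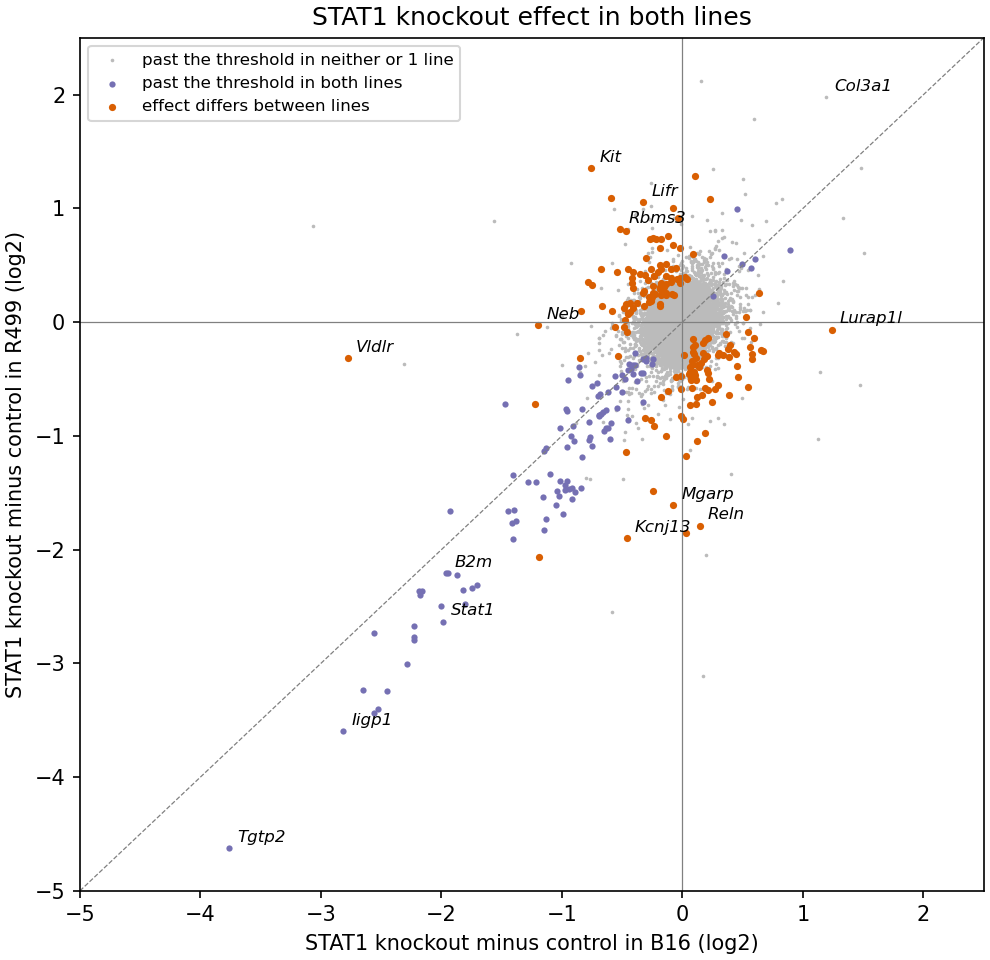
STAT1 knockout minus control in B16 (horizontal axis, log2) against the same difference in R499 (vertical axis, log2) for the 13806 tested genes; purple points passed the threshold in both lines, orange points had an effect that differed between the lines, and the dashed line marks equal effects. Tgtp2 (−3.77 and −4.62), Iigp1, B2m and Stat1 lie in the lower left, while Vldlr (−2.78 and −0.32), Kit (−0.76 and 1.35) and Reln (0.14 and −1.79) lie away from the line of equal effects.

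Control cells of the lines differed in 752 genes, 421 higher and 331 lower in R499. Kalrn, a Rho guanine nucleotide exchange factor (chromosome 16, 33969073 to 34573532), was 20-fold higher in R499 (log2 difference 4.32, SE 0.206, adjusted p = 2.56e-09, n = 3 and 3). Dcdc2a (1.95), Reln (1.91, SE 0.125), the RNA demethylase gene Fto (1.48), Mgarp (1.43) and Irf4, a transcription factor of lymphocytes and pigment cells (1.41, SE 0.0863), were also higher. Neb, the giant muscle protein nebulin (−2.49, SE 0.197), the glycosyltransferase gene Galnt6 (−1.82), the ubiquitin ligase gene Mgrn1, which acts in pigment type switching (−1.45), the neuropilin gene Nrp2 (−1.27), the antiproliferative gene Btg2 (−1.17) and Mid1 (−1.12) were lower.

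Interferon and antigen presentation genes stood higher on average in R499 than in B16 control cells, by less than the knockout lowered them, and the groups overlapped. Mean levels of the type I interferon, interferon gamma and MHC class I lists were 7.052, 7.78 and 7.956 in B16 control replicate 5, above 6.77, 7.003 and 7.77 in R499 control replicate 2. Of 40 type I interferon genes 8 were higher (17 adjusted over the list alone), with a median of 0.34 and examples in Rtp4 (0.64), Trim25 (0.60), Oas1a (0.48, SE 0.103, adjusted p = 0.0122) and Samd9l (0.47). Of 19 MHC class I genes 7 were higher and the chaperone gene Pdia3, named after its value was seen, was lower (10 and 1 adjusted over the list alone): the immunoproteasome genes Psmb8 (0.90, SE 0.181) and Psmb9 (0.63, SE 0.101), B2m (0.83, SE 0.195, adjusted p = 0.0194), H2-D1 (0.81), H2-K1 (0.73) and H2-M3 (0.25) were among them. The number of higher MHC class I genes was 3 without B16 control replicate 1 or 4 or R499 control replicate 1, 4 without R499 control replicate 4 and 11 without B16 control replicate 5. The number of higher type I interferon genes was 0 without B16 control replicate 4 or R499 control replicate 1, 1 without B16 control replicate 1 or R499 control replicate 4, 13 without B16 control replicate 5 and 18 without R499 control replicate 2. The calls of Trim25 ended in 8, of Samd9l in 6, of B2m, H2-K1, Irf9 and Rtp4 in 5 and of H2-D1 in 4 of 18 alternatives. Those of Oas1a ended in 3 and of Psmb8 and H2-M3 in 1 of 17. None of 21 interferon gamma genes passed (also none adjusted over the list alone), with a median of 0.48. The lists had camera adjusted p = 3.13e-08, 2.05e-05 and 9.9e-05, and adjusted p = 0.391, 0.292 and 0.427 with an estimated correlation. With fry they had adjusted p = 0.108, 0.0244 and 0.17 in the same order. Stat1 was at 0.57 (SE 0.273, adjusted p = 0.275), Cd274 at 0.67 (adjusted p = 0.107), Tap1 at 0.32 (adjusted p = 0.536) and Irf1 at 0.28 (adjusted p = 0.516). Irf9 was higher by 0.43 (SE 0.104, adjusted p = 0.0217), the 1 changed gene among 15 JAK-STAT components (also 1 adjusted over the list alone; list adjusted p = 0.241 with an estimated correlation).

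Other lists that differed between control cells held few changed members each. Their calls ended for Uqcrfs1 in 10, Pdk1 in 9, Cdkn1a in 8, Sesn2 and Zfp36 in 7, Ndufb5, Slc24a5 and Ier2 in 6, Jun and Trib3 in 5 and Hsp90b1 and Atp5b in 1 of 18 alternatives. Higher in R499 were Egln3 (0.65) and Pdk1 (0.46) of 25 hypoxia and glycolysis genes (3 adjusted over the list alone), Atp5b (0.47), Ndufb5 (0.35) and Uqcrfs1 (0.34) of 23 oxidative phosphorylation genes (also 3), and Trpm1 (0.53) and Slc24a5 (0.40) of 20 pigment genes, where Kit was lower (6 higher and 1 lower adjusted over the list alone). Their adjusted p was 0.391 with an estimated correlation and 0.12 with fry for each. Lower in R499 were Trib3 (−0.63), Hsp90b1 (−0.45) and Sesn2 (−0.42) of 19 stress response genes, where Vldlr was higher (9 lower and 1 higher adjusted over the list alone). Of 16 immediate early genes Nr4a1 (−0.93, SE 0.12), Jun (−0.43), Zfp36 (−0.35) and Ier2 (−0.30) were lower (7 lower and 1 higher adjusted over the list alone). Of 13 p53 targets Btg2, the cell cycle inhibitor gene Cdkn1a (−0.69) and Eda2r (−0.55) were lower and Mdm2, named after its value was seen, was higher by 0.35 (4 lower and 1 higher adjusted over the list alone). These lists had adjusted p = 0.258, 0.258 and 0.241 with an estimated correlation, and adjusted p = 0.0239, 0.0141 and 0.00504 with fry. Fibroblast, endothelial and macrophage markers had medians of −0.18, −0.12 and −0.07 (macrophage mean 0.17), and none of these lists passed camera (adjusted p = 0.0621, 0.0642 and 0.653). Of the 5 macrophage markers 1 was higher in R499 (also 1 adjusted over the list alone), and no fibroblast or endothelial marker passed. The count of 752 was 341 without B16 control replicate 1, 376 without B16 control replicate 4, 385 without R499 control replicate 1, 431 without R499 control replicate 2 and 1953 with library quality weights.

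Knockout cells of the lines differed in 2351 genes, 1144 higher and 1207 lower in R499. The balance was 892 and 1403 after centring on library medians, 1066 and 1375 under quantile normalization, and turned to 1745 and 1429 without B16 knockout replicates 4 and 5 and to 675 and 602 with the small RNA covariate. Kalrn was again far higher (4.15, SE 0.16, adjusted p = 3.52e-11, n = 5 and 5), followed by Vldlr (3.06, SE 0.128, 8.33-fold), Lifr (1.82, SE 0.0854), Ntrk3 (1.79), Dcdc2a (1.77) and the caveolin gene Cav1 (1.75). Galnt6 (−2.60, SE 0.0996), Nrp2 (−2.17, SE 0.0873), Mgrn1 (−1.90), Mid1 (−1.61), Tent5a (−1.34) and Neb (−1.32) were lower. Cd274 was higher by 1.08 in R499 knockout cells (SE 0.178, adjusted p = 0.000475) and B2m by 0.58 (SE 0.151, adjusted p = 0.0133), whereas Stat1 (−0.08, adjusted p = 0.845), H2-K1 (0.17, adjusted p = 0.462), Irf9 (−0.015) and Tap1 (−0.05) did not pass. Tyr (−0.38, SE 0.0594, adjusted p = 0.000343) and Mitf (−0.29, SE 0.0841, adjusted p = 0.0247) were lower. The call of Mitf ended in 6 of 23 alternatives, quantile normalization (−0.16, adjusted p = 0.137) and the omission of B16 knockout replicate 1 or 3 or R499 knockout replicate 1, 4 or 5.

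The interferon lists had medians near 0 between knockout cells. Of 40 type I interferon genes 3 were higher and 1 lower (the same counts adjusted over the list alone), with a median of 0.02 that was −0.0036 under quantile normalization. Of 19 MHC class I genes B2m was higher and 4 were lower (2 and 4 adjusted over the list alone, median 0.02, mean −0.04). Of 21 interferon gamma genes Cd274 was higher and the tRNA synthetase gene Wars lower (−0.38; also 1 and 1 adjusted over the list alone). Wars and the 4 lower MHC class I genes, Pdia3, Calr, Erap1 and H2-T23, were named after their values were seen. None of these 3 lists passed camera (adjusted p = 0.833 for each). Of 19 genes of the integrated stress response and ER stress 12 were lower and Vldlr was higher (13 and 1 adjusted over the list alone), with a median of −0.43. The ER chaperone genes Hspa5 (−0.81, SE 0.122) and Hsp90b1 (−0.67, SE 0.0756), Trib3 (−0.74) and Chac1 (−0.57) were examples, and the list had camera adjusted p = 3.57e-05 and adjusted p = 0.376 with an estimated correlation. Of 30 cell cycle genes 8 were higher (9 adjusted over the list alone), including Ccnb1 (0.44), Foxm1 (0.39), Mki67 (0.29) and Mcm7 (0.29), the calls of Foxm1 and Mki67 ending in 1 of 23 alternatives each, with camera adjusted p = 7.38e-05 and adjusted p = 0.879 with an estimated correlation. The NF-kB list held no changed gene and the dedifferentiated, mesenchymal-like list 3 higher and 2 lower of 17 (4 and 2 adjusted over the list alone, mean 0.07 with a median of −0.00038), and neither passed camera (adjusted p = 0.953 and 0.833).

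The line differences of control and knockout cells share no library. In both genotypes 240 genes were higher in R499 (34.9 for independent lists) and 187 lower (28.9). Simulations with lists filled by rank gave at most 60 and 51. Of the 240, 3 belonged to the interferon and MHC class I lists. Across genes the differences correlated at 0.534, with a covariance of 0.0276. The count of 2351 was 1277 with small RNA level as a covariate, an alternative chosen after seeing the data.

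Genes higher in R499 control cells were then set against genes that fell in R499 knockout cells. Reln was higher by 1.91 in R499 control cells and fell by 1.79 in knockout cells, Mgarp was at 1.43 and −1.61, Kcnj13 at 1.33 and −1.90, the actin regulator gene Carmil2 at 1.20 and −1.17, Ralgps2 at 1.178 and −0.82, Zfp935 at 0.98 and −0.97, Psmb8 at 0.90 and −1.38 and B2m at 0.83 and −2.21. Of these 8 genes, B2m (0.58, adjusted p = 0.0133) and Ralgps2 (0.37, adjusted p = 0.0239) remained higher in R499 among knockout cells. In all 112 of the 421 genes higher in R499 control cells fell, and 309 did not. Of the 112, 15 belonged to the interferon and MHC class I lists, which hold 80 tested genes. These lists do not hold every interferon-linked gene, since Irf9 is among the 112 and outside them. The median difference of the 112 between the lines was 0.47 in control cells and 0.05 in knockout cells, where 33 were still higher in R499 and 3 lower. Part of this drop is built in, since the 112 were picked as low in the same R499 knockout libraries. Of all 421 genes, 240 stayed higher in R499 among knockout cells.

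The R499 control libraries enter both lists with opposite sign, and chance alone links them. The overlap of 112 compares with 13.5 for independent lists. Simulations with shared controls and no effect gave a mean of 116 and at most 138, for lists filled by rank to the observed lengths. The covariance of the differences was −0.0194 against −0.00912 simulated, a difference of −0.0103, and the correlation across genes was −0.385 against −0.555. With 3 libraries the controls were too few to split. Lists filled by rank need not hold genes past the threshold, so the simulations cannot say what overlap shared controls give among called genes. No conclusion is drawn from the size of the overlap. Genes that fell in B16 knockout cells share other libraries with the line comparison, in a direction that works against such an overlap. Of the 421 genes higher in R499 control cells 36 fell in B16 knockout cells, against 6.68 for independent lists. The simulations gave at most 2, but they were filled by rank here too and have the same limit for called genes. Of the 36, 11 belonged to the interferon and MHC class I lists, among them B2m, H2-D1, H2-K1, Rtp4 and Trim25. The overlap of 112 was 51 without B16 control replicate 1, 57 without B16 control replicate 4, 47 without R499 control replicate 1, 72 and 71 without R499 knockout replicate 3 and 5, 73 after centring on library medians and 362 with library quality weights.

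**Figure D4:**
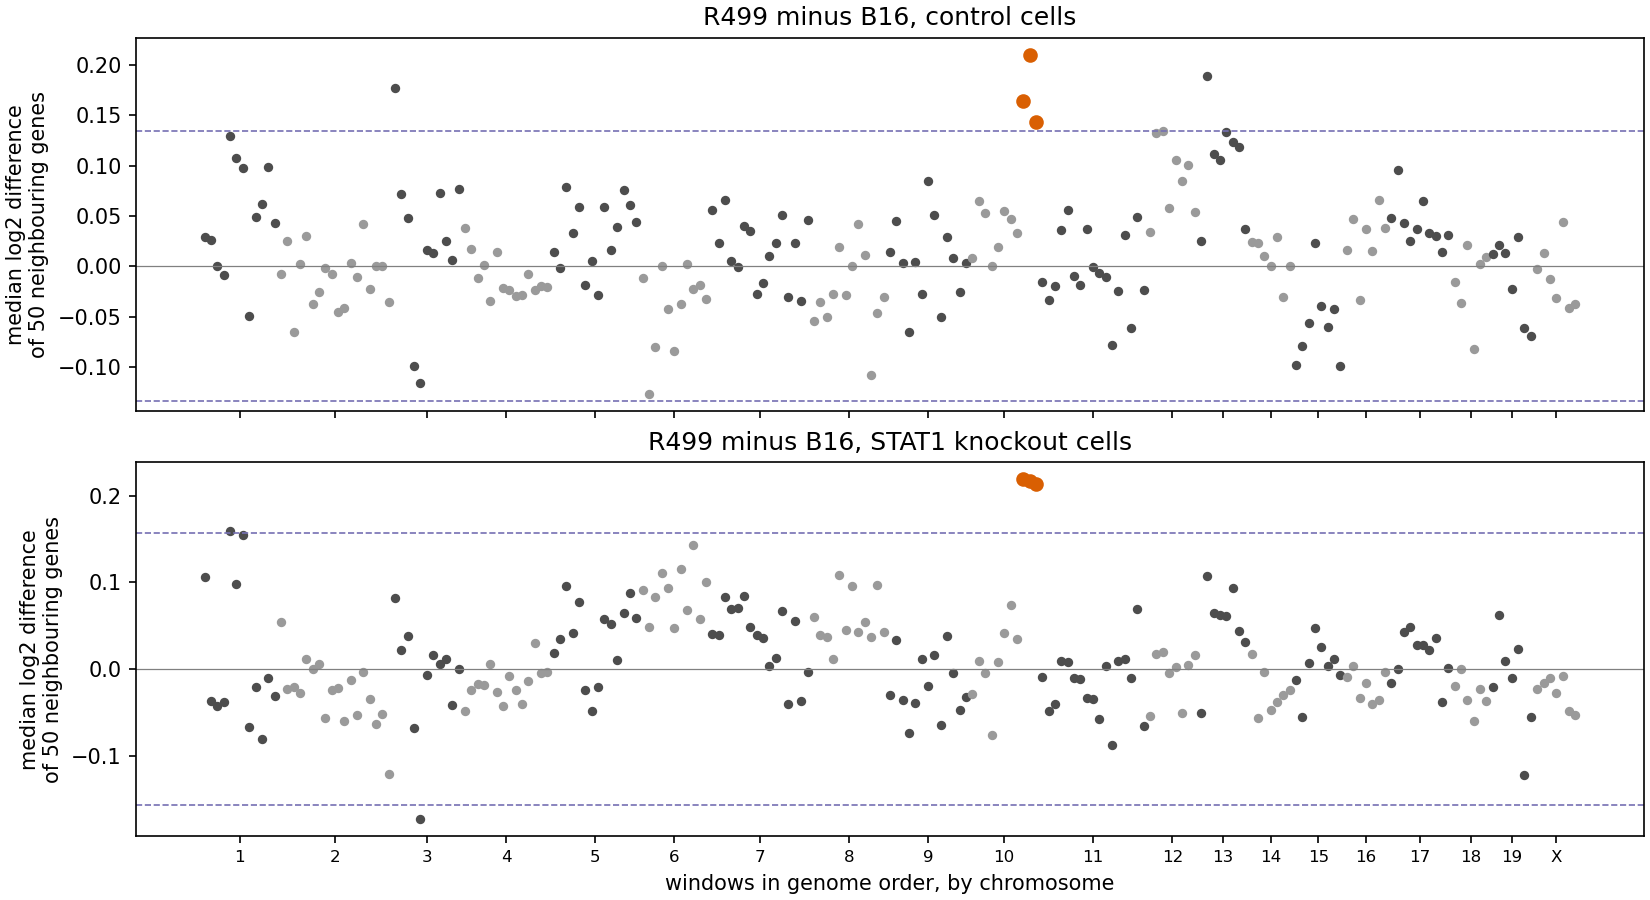
Median log2 difference between R499 and B16 over windows of 50 neighbouring protein-coding genes along the genome, for control cells (top) and STAT1 knockout cells (bottom); dashed lines give the largest value in 1000 shuffled gene orders (0.134 and 0.157). Orange points are the 3 adjoining windows of chromosome 10 that lie beyond the lines in both panels, with medians of 0.16, 0.21 and 0.14 in control cells and 0.22, 0.22 and 0.21 in knockout cells.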

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

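The tests of fibroblast RNA and of a lower tumor cell share, and the small RNA covariate as an alternative, were chosen only after the result was seen.

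Of 150 checks for a library far from the 4 others of its knockout group, 14 found one, and chance flags about 1 in 20 groups. In B16 knockout cells these were, on the rlog scale, Pecam1 in replicate 2 (4.896), Vldlr (6.263) and Lurap1l (5.265) in replicate 3, Zfp935 in replicate 1 (4.023), the mean of the dedifferentiated, mesenchymal-like genes in replicate 4 (7.185) and the mean of the fibroblast markers in replicate 3 (6.408). In R499 knockout cells they were Tyr (14.18) and Dcdc2a (8.467) in replicate 4, Irf1 (6.139), Nrp2 (9.394) and Reln (4.225) in replicate 2, and Tgtp1 in replicate 5 (5.482). The means of the type I interferon list (5.87) and of the mitochondrially encoded genes (12.99) in R499 knockout replicate 4 were the last 2.

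The knockout effect of 20 named genes differed between the lines in a test of the difference itself. It was higher in R499 for Vldlr (2.46), Kit (2.11), Lifr (1.381), Rbms3 (1.331), Cacna1c (1.271), Ntrk3 (1.181), Foxm1 (0.7687), Mki67 (0.5098), Ezh2 (0.4891) and Pbrm1 (0.3908). It was lower for Reln (−1.933), Mgarp (−1.535), Kcnj13 (−1.433), Lurap1l (−1.304), Tent5a (−1.245), Carmil2 (−1.206), Oca2 (−0.6284), Psmb9 (−0.5973), mt-Co1 (−0.5837) and Tyr (−0.5043). Among alternatives, left-out libraries included, the call ended for Pbrm1 in 17 of 28, Oca2 in 12 of 28, Ntrk3 in 11 of 28, Psmb9 and mt-Co1 in 9 of 27 each, Ezh2 in 8 of 28, Tyr and Mki67 in 3 of 28 each, Foxm1 and Cacna1c in 2 of 28 each, and Lifr in 1 of 28, the other deposited table. It held in each alternative run for Vldlr, Kit, Rbms3, Reln, Mgarp, Kcnj13, Lurap1l, Tent5a and Carmil2. For Reln, Mgarp, Kcnj13 and Carmil2 the differing effect largely restates the difference between control cells of the lines.

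Fibroblast markers had a median difference of 0.61 in R499 knockout cells, where 3 of 10 passed (list adjusted p = 0.217 with an estimated correlation), and the 10 tested markers deviated together between libraries of a group, with a median pair correlation of 0.778 against 0.0019 (95th percentile 0.135) for random sets of like mean. This goes with RNA of fibroblasts among the sorted cells, but genes regulated together would also deviate together, so expression by the tumor cells themselves stays open. The correlation estimated by camera was 0.622 for this list and 0.716 for the interferon gamma list. The deviations were pooled over all groups, with B16 knockout replicate 3, flagged for this list, included. All 10 markers lie above 3 in control cells of both lines, Col1a1 at 4.32 in B16 and 4.11 in R499. The filter at a mean above 3 makes this likely, so it cannot tell the 2 sources apart. The cells were sorted, and whether the gate removed fibroblasts is not given in the labels. The small RNA level as the source of the rise is argued against, since the median was 0.676 with that level as a covariate. Other parts of library composition were not tested. With fry the fibroblast and endothelial lists had adjusted p = 0.0191 and 0.00416. A lower share of tumor cells, which would raise all other cell types alike, cannot be told apart: the endothelial markers had a median of 0.185, where 3 of 8 passed (list adjusted p = 0.103 with an estimated correlation), and the macrophage markers moved by −0.0167 (SE of the median 0.0818), but 3 of those 5 lie near the filter, with means of 3.34, 3.37 and 3.87.

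Interferon and MHC class I genes stood higher on average in R499 than in B16 control cells, with a median of 0.357 for the MHC class I list, but no call with an estimated correlation (adjusted p = 0.391 for type I interferon, 0.427 for interferon gamma and 0.292 for MHC class I genes), and B16 control replicate 5 lay above R499 control replicate 2. With fry, adjusted p was 0.108 for type I interferon, 0.17 for interferon gamma and 0.0244 for MHC class I genes, so the last list kept its call. A single library as the source of the whole difference is argued against, since the median of the MHC class I list stayed between 0.273 and 0.574 without each control library in turn. The number of changed members depended on single libraries. RNA of immune cells among the sorted cells cannot be told apart. Ptprc, Lyz2, Cd74, Tyrobp and Fcer1g moved by −0.0429 on average (SE 0.0448), which met the bound of 0 or below set in advance, but by less than the SE. They lie near the floor, where rlog draws differences towards 0. The rule was changed after the values were seen: the margin of the SE and the condition on the floor were not part of that bound. No biological explanation was tested.

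Differences between the lines may in part follow gene copy number. Of 217 windows of 50 neighbouring genes, 3 adjoining windows of chromosome 10 (88452745 to 128411492) lay beyond all shuffled gene orders in both genotypes. In all, 5 windows lay beyond in control cells, 5 in knockout cells and 1 for the difference of knockout effects. Chromosome 6 had a median of −0.032 between control cells (10 genes higher, 28 lower) and 0.0874 between knockout cells (104 and 43). Chromosome 8 had −0.0295 and 0.0543, and chromosome 12 had 0.0866 and 0.000167. Regional shifts may therefore also enter the difference of knockout effects. Window medians of the genotypes correlated at 0.459, under the 0.5 set in advance, and without DNA a copy number change and regional regulation cannot be told apart. All 12 named genes with the largest differences between control cells had neighbours whose median lay below the share of the gene's own difference set in advance. The neighbours reached at most 0.128 of that difference, for Irf4. The choice of genes fixed this outcome. The smallest of the 12 differences was that of Mid1 (−1.119), while the largest window median between control cells was 0.21. It shows only that neighbours moved less than these genes, and no cause is excluded.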

How the results depend on the processing

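Of the alternatives in this part, these tests were chosen only after the result was seen: protein-coding genes only, the small RNA covariate, and B16 knockout replicates 4 and 5 left out together. Depth is unknown because no counts were analysed here, so what depth limits could not be measured, and rlog understates changes of weak genes. Leaving out 1 library at a time gave 170 to 327 genes for knockout in B16, 364 to 1069 in R499, 341 to 881 between control cells, 1811 to 2689 between knockout cells, 81 to 213 for the difference of effects and 47 to 129 for the overlap. Omission moved the count by over 1.5 times for B16 control replicates 4 and 5 (B16 knockout), for R499 control replicates 1 and 2 and knockout replicates 4 and 5 (R499 knockout), for B16 control replicates 1 and 4 and R499 control replicates 1 and 2 (control cells), for B16 control replicate 4 and R499 control replicate 1 (difference of effects), and for B16 control replicates 1 and 4, R499 control replicate 1 and R499 knockout replicates 3 and 5 (overlap). Library quality weights gave 586 and 1963 genes for knockout in B16 and R499, 1953 between control cells, 669 for the difference of effects and 362 for the overlap. Median centring gave 73 for the overlap, the small RNA covariate 1277 between knockout cells, B16 libraries alone 192, which uses fewer libraries to estimate the spread, and B16 without knockout replicates 4 and 5 together 461. Blocking on replicate number, which spends degrees of freedom, gave 440 for knockout in R499, 494 between control cells and 100 for the difference of effects. Same-numbered control and knockout libraries correlated above 0.1 in their residuals in 0 of 3 cases in each line. Between B16 and R499 knockout libraries 3 of 5 same-numbered pairs did, with a mean of 0.158 against −0.0406 for different numbers, so a factor shared by number stays open there; the block gave 2200 genes between knockout cells. Of 2768 gene results without 1 library, 2447 kept direction and side of the threshold, 264 lost the call, 40 gained one and 17 changed sign. Kept, lost, gained and changed in sign were 236, 36, 10 and 1 of 283 with the block, 176, 29, 8 and 0 of 213 with only the groups compared, 243, 2, 37 and 1 with quality weights, 267, 16, 0 and 0 without a filter, 261, 10, 5 and 7 with the small RNA covariate, 271, 6, 5 and 1 under quantile normalization, 276, 6, 1 and 0 under median centring, 276, 3, 4 and 0 with robust variance, 280, 2, 1 and 0 without a trend, and 280, 0, 3 and 0 with protein-coding genes, each of 283. They were 260, 12, 2 and 1 of 275 in the other table, 239, 1, 1 and 0 of 241 with means above 5, and 145, 5, 4 and 1 of 155 without B16 knockout replicates 4 and 5. The sign changed for genes without a call, and the cause was not tested. Quantile normalization gave Tyr −0.03659 for knockout in B16, quality weights Irf9 0.003744 and the other table Pecam1 0.002374 between knockout cells, and the block Irf1 −0.06695 for the difference of effects. With the small RNA covariate Lgals9 was −0.003401 between control cells, and Col1a1 0.1073, Irf9 0.1205, Pecam1 0.1103, Stat1 0.1784, Tap1 0.1574 and Oas1a 0.0218 between knockout cells. Without B16 knockout replicates 4 and 5 Stat1 was 0.03852 between knockout cells. Without 1 library at a time, values between control cells ran from −0.1093 to 0.1805 for Lgals9 and −0.07619 to 0.3537 for Ifit1, and the difference of effects of Irf1 from −0.1378 to 0.3425. Between knockout cells they ran from −0.04344 to 0.01566 for Irf9, −0.06766 to 0.01956 for Pecam1, −0.1037 to 0.02324 for Tap1, −0.1384 to 0.06135 for Col1a1 and −0.1937 to 0.0004374 for Stat1. Of 100 list results, 38 lost the call with an estimated correlation and none changed direction. With fry 23 lost the call and 5 gained one. JAK-STAT gained it for knockout in B16 (fry adjusted p = 0.0152) and R499 (0.00515) and between knockout cells (0.00243). The p53 targets gained it for knockout in R499 (0.0334) and between knockout cells (0.00144). Another 5 without a call in either test had the opposite direction: for knockout in B16 NF-kB (median 0.0335), melanocyte pigment (0.0437), stress response (0.0415) and macrophage (−0.00168), and for the difference of effects stress response (−0.0232). The median changed sign in 5 under quantile normalization: melanocyte pigment −0.00637 and macrophage 0.00457 for knockout in B16, and type I interferon −0.00358, interferon gamma −0.0148 and chromatin −0.0143 between knockout cells. It changed in 5 with the block: macrophage 0.0059 for knockout in B16, JAK-STAT −0.0463 for knockout in R499, cell cycle 0.00474 between control cells, and JAK-STAT −0.0449 and macrophage −0.0581 for the difference of effects. Without a filter it changed in 6: macrophage 0.000899 for knockout in B16, NF-kB 0.021 for knockout in R499, NF-kB −0.00901 between control cells, mesenchymal-like 0.0043 between knockout cells, and NF-kB 0.0326 and macrophage −0.0042 for the difference of effects. With the small RNA covariate it changed in 10: JAK-STAT −0.0341 and stress response 0.0207 for knockout in R499, cell cycle 0.0309 and mitochondrially encoded −0.0646 between control cells, melanocyte pigment 0.0119, mesenchymal-like 0.0893, hypoxia −0.028, chromatin −0.0642 and macrophage 0.0487 between knockout cells, and macrophage −0.0266 for the difference of effects.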

Other observations

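The counts over other splits of the libraries were tests set in advance, and the genes named in the next 2 paragraphs were chosen only after the result was seen, without further tests.

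Osmr, the oncostatin M receptor subunit, rose after knockout in B16 (0.89, SE 0.141) and R499 (0.64, SE 0.141) and was higher in R499 control cells (0.61, SE 0.158, adjusted p = 0.0304). Lifr was higher in R499 control cells by 0.43 (adjusted p = 0.0289) and in R499 knockout cells by 1.82 (SE 0.0854). Socs3, an inhibitor of cytokine signalling, rose in R499 knockout cells (0.54) and was higher in R499 than B16 knockout cells (0.85).

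Of the 240 genes higher in R499 in both genotypes, Irf4 (1.41 in control and 1.33 in knockout cells), Cav1 (1.23 and 1.75), the secreted phosphoprotein gene Spp1 (1.21 and 0.80), the laminin gene Lamb1 (0.80 and 1.74) and the actin bundling gene Fscn1 (0.71 and 0.90) were among those outside the interferon and MHC class I lists. Mgrn1 and Galnt6 were lower in R499 in both genotypes. The first 3 principal components held 31%, 19% and 12.6% of the variance. The first largely parted the lines: all R499 libraries were negative (−0.306 to −0.0364). All B16 libraries except knockout replicate 4 (−0.061) were positive, with knockout replicate 2 furthest out (0.633). The second parted control from knockout libraries, and B16 knockout replicates 4 and 5 stood apart on the third.

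Other splits of the libraries were counted for each number of changed genes. For knockout in B16, 2 of 56 splits gave as many as the real 297, the real split included, and the highest other gave 435. That split set B16 knockout replicates 1, 2 and 3 against the controls with replicates 4 and 5, which points to a structure among the B16 knockout libraries. For knockout in R499, 1 of 56 splits gave 705 and the highest other gave 578. For R499 against B16 knockout cells, 1 of 100 splits gave 2351 and the highest other 635, and for the difference of effects 1 of 100 gave 176 and the highest other 69. A share of splits under 0.05 argues against chance for knockout in R499 and for R499 against B16 knockout cells. For knockout in B16 the share was also under 0.05. Another split gave more genes than the real one there, so the splits do not exclude chance for the count of 297. Of the genes that fell in B16, 112 also fell in R499, whose comparison shares no library, against 7.03 for independent lists. This argues against chance for those genes as a set. Reassignments for the difference of effects mix the lines. The line differences then widen the spread and lower the counts, so these reassignments cannot decide on the difference of effects. For genes higher in R499 control cells that fell in R499 knockout cells, 2 of 100 reassignments gave an overlap of 112 or more. The highest other gave 136. Chance is not excluded, since the shared controls link the 2 lists. The simulations, filled by rank with a mean of 116, cannot measure that link among called genes. The 6 control libraries make 10 splits, too few for a share under 0.05; the real split, 1 of the 10, gave 752 and the highest other 63.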
